A study of Homo sapiens with 12 samples.

How the data were processed

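RNA from MCF-7 cells in 4 groups of 3 (luciferase or NMNAT1 shRNA, vehicle or E2) was measured on 8 Affymetrix U133A 2.0 and 4 U133 Plus 2.0 arrays. The deposited values are on a log2 scale, relative to the other arrays. Per the series' design text, the authors kept the probe sets common to both platforms, took log2, centred each array and then each gene on its median within a platform, and adjusted for platform with parametric ComBat. GCOS is named in the submitters' processing notes. In the deposited values the means of each probe set, not the medians, were 0 within a platform (largest absolute mean 2.5e-05 on U133 Plus 2.0 and 3.75e-05 on U133A 2.0). Centring removes the level of each probe set, so neither signal over background nor dim probe sets can be seen, ComBat can shrink differences, and array medians ran from -0.02 to 0.08. No further normalization was applied.

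Groups came from the sample labels. Per the design text, the replicate number marks an independently prepared cell population with its matched luciferase control. Same-numbered arrays were therefore treated as pairs in the counts of matched pairs, the sign-flip tests, the replicate blocks and some splits. The main fit held no term for the pair or the population. As a check, deviations from group means correlated between same-numbered arrays at a mean of -0.04 for replicate 1, -0.33 for replicate 2 (where centring over 4 arrays forces a negative value) and -0.01 for replicate 3, against -0.11 between different numbers on the same platform. No 2 arrays of a group were identical (smallest SD of a difference 0.769).

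All 22232 probe sets with values on the 12 arrays were fitted with limma 3.58.1 in R 4.3.3, with group and platform as terms, 7 residual degrees of freedom, empirical Bayes with a trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. The trend was fixed before the data were examined; in centred values the mean carries no signal level. Contrasts were the E2 effect (averaged and per shRNA), the shRNA effect (averaged and per treatment) and the interaction. Errors of changes are standard errors. Every group held both platforms in the same proportion, and probe set means were 0 within a platform apart from rounding. The platform coefficient was therefore 0 to the same precision. Leaving the platform term out keeps the log2 changes and residuals and only adds a degree of freedom that centring had used. Counts without this term therefore rest on too many degrees of freedom and show no platform difference. Planned filters on dim probe sets and a floor on low signals could not be run, since the values hold no signal level. Probe sets were named from the platform annotation, which lists 1 gene symbol for 19071, several for 1043 and none for 2118. Of the 19071, 19059 matched the GRCh38.p14 gene table by gene identifier and 0 symbols changed. Only probe sets with 1 symbol were named. No coordinates are given, since no genome build is named for the values.

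The rule for named genes was set before the data were examined. For each averaged effect it took, among probe sets that passed and changed the same way in all 6 matched pairs, 1 per gene, the 12 largest rises and falls. Where fewer than 5 passed in a direction it took the 5 with the lowest p, and for the interaction the 10 genes with the lowest p. Members of gene lists were chosen by lowest p, with those needed to say what moved. The 24 lists were fixed beforehand and tested with camera (preset correlation 0.01) on 11963 genes, adjusted over the lists of a contrast. The planned choice of the brightest probe set per gene needs a signal level, so the mean over a gene's probe sets, which had been listed beforehand as another choice, was used. List members that rose or fell passed over all genes, and counts adjusted over the list alone are given beside them. RNA quality was tested with exact two-sided sign-flip tests, over 6 pairs for E2 and over 3 pairs of populations, with vehicle and E2 averaged, for the shRNA.

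The fit was tested on simulated data with the residual spread of these 22232 probe sets and 200 changed ones, in 3 simulations per contrast. For the averaged E2 effect 37.3% of 2-fold and 54.5% of 4-fold changes were recovered, for the averaged shRNA effect 42.3% and 50.5%, and for E2 in luciferase shRNA cells 30.3% and 52.5%. Among calls, false ones made up 4.74%, 5.50% and 4.57%. The simulated arrays were independent, whereas the 2 arrays of a real population had a consensus correlation of 0.146. The rates for the averaged shRNA effect can therefore be too favourable. All these rates hold for 200 changed probe sets. With fewer changes the adjusted threshold is harder to pass, and with more it is easier. In 10 simulations of 11963 genes with the ribosome biogenesis list shifted by 0.5 on the log2 scale, camera called that list 10 times and 0 of 230 other lists. The simulated genes were independent of each other, so these counts do not test the preset correlation. The alternatives were quantile normalization, no platform term, no trend, array weights, replicate blocks, only the groups compared, a threshold of 0.1, leave-outs, other list tests and, added after seeing the data, recentred medians, robust empirical Bayes, a 3' to 5' covariate, the probe set with the lowest residual SD and, for the averaged shRNA effect, the mean of the 2 arrays of each population or the population as a random block.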

Results

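Expression was measured on Affymetrix arrays in MCF-7, an estrogen receptor-positive human breast cancer cell line, in a 2 by 2 design. The cells stably carried a retroviral shRNA against NMNAT1, the nuclear enzyme that makes NAD+ from nicotinamide mononucleotide, or a control shRNA against luciferase, a firefly enzyme that human cells lack. After 72 hours without hormone they received 1e-07 M estradiol (E2) or the ethanol vehicle for 3 hours. Each of the 4 groups held 3 arrays, 1 from each of 3 independently prepared cell populations, and the populations with the NMNAT1 shRNA had matched luciferase shRNA populations with the same replicate number. Replicate 2 was measured on U133 Plus 2.0 arrays and replicates 1 and 3 on U133A 2.0 arrays. The values are log2 expression relative to the other arrays of the same platform for 22232 probe sets, so they carry no absolute level, and the number of arrays limits the precision.

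The targeted gene could not be used to check the labels. NMNAT1 has 3 probe sets listed for the U133 Plus 2.0 array and 0 for the U133A 2.0 array, and 0 were among the probe sets analysed here. The size of the knockdown is therefore not analysed here. The neuronal family member NMNAT2 (209755_at) had a log2 difference of -0.05 ± 0.56 (SE) between NMNAT1 and luciferase shRNA cells, which did not pass the test (adjusted p = 0.985).

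The first comparison asked what 3 hours of E2 did in these cells, averaged over both shRNAs. The largest rise was in FOS, a subunit of the AP-1 transcription factor, which was 33.3-fold higher with E2 (log2 5.06 ± 0.22 SE, adjusted p = 2.15e-05, higher in 6 of 6 matched pairs). Among the other large rises, the calcium channel TRPC6 rose 14.8-fold, the beta-1 adrenergic receptor ADRB1 11.5-fold, the purinergic receptor P2RY2 7.55-fold and the Wnt receptor FZD7 6.43-fold. The granzyme B inhibitor SERPINB9 rose 11.5-fold, the Wnt ligand WNT4 6.81-fold, the retinoic acid-degrading enzyme CYP26B1 6.64-fold and the transcription factor EGR3 6.34-fold. MYOT, SEMA3G and NSG1 completed the 12 largest rises at 12.5-fold, 7.11-fold and 6.85-fold. The largest fall was in RNF43, an E3 ubiquitin ligase that removes Wnt receptors, which was 11.9-fold lower (log2 -3.57 ± 0.39). ID1, ID2 and ID3, inhibitors of basic helix-loop-helix transcription factors, were 5.12-fold, 4.79-fold and 3.81-fold lower, and DKK1, a secreted Wnt antagonist, was 3.74-fold lower. The sialyltransferase ST3GAL6 (6.65-fold), the microfibril protein FBN2 (5.63-fold), LDB2 (5.06-fold), the protease MMP12 (4.85-fold), PURG (4.53-fold), CALHM2 (4.40-fold) and the ephrin ligand EFNA1 (4.13-fold) were also lower. For ST3GAL6, 1 of 4 probe sets passed and 2 had the other sign, for NSG1 1 of 3 passed, and for SERPINB9 and FBN2 1 of 2. WNT4, LDB2, MMP12, PURG and CALHM2 passed in neither kind of cells alone (limma adjusted p between 0.0564 and 0.474). In replicate 3 of the luciferase shRNA cells WNT4 moved only from -0.23 to -0.18. By the rule that chose them, each of these 24 genes passed and changed the same way in 6 of 6 pairs, with adjusted p from limma of at most 0.0483.

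In all, 989 of the 22232 probe sets passed for E2, 600 higher and 389 lower, and 943 of them changed the same way in all 6 pairs. They named 456 genes with a rise and 298 with a fall, 3 of them in both lists, and 348 of the probe sets changed more than 2-fold. With each of the 6 cell populations as a block, 577 probe sets passed, 536 of them shared. Without replicate 1, 2 or 3 the number was 96, 175 or 58. It was over 1.5 times lower without replicate 2 or 3 of the luciferase vehicle group (562 and 632), replicate 2 of luciferase E2 (607) and replicate 2 or 3 of NMNAT1 vehicle (626 and 655).

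**Figure D1:**
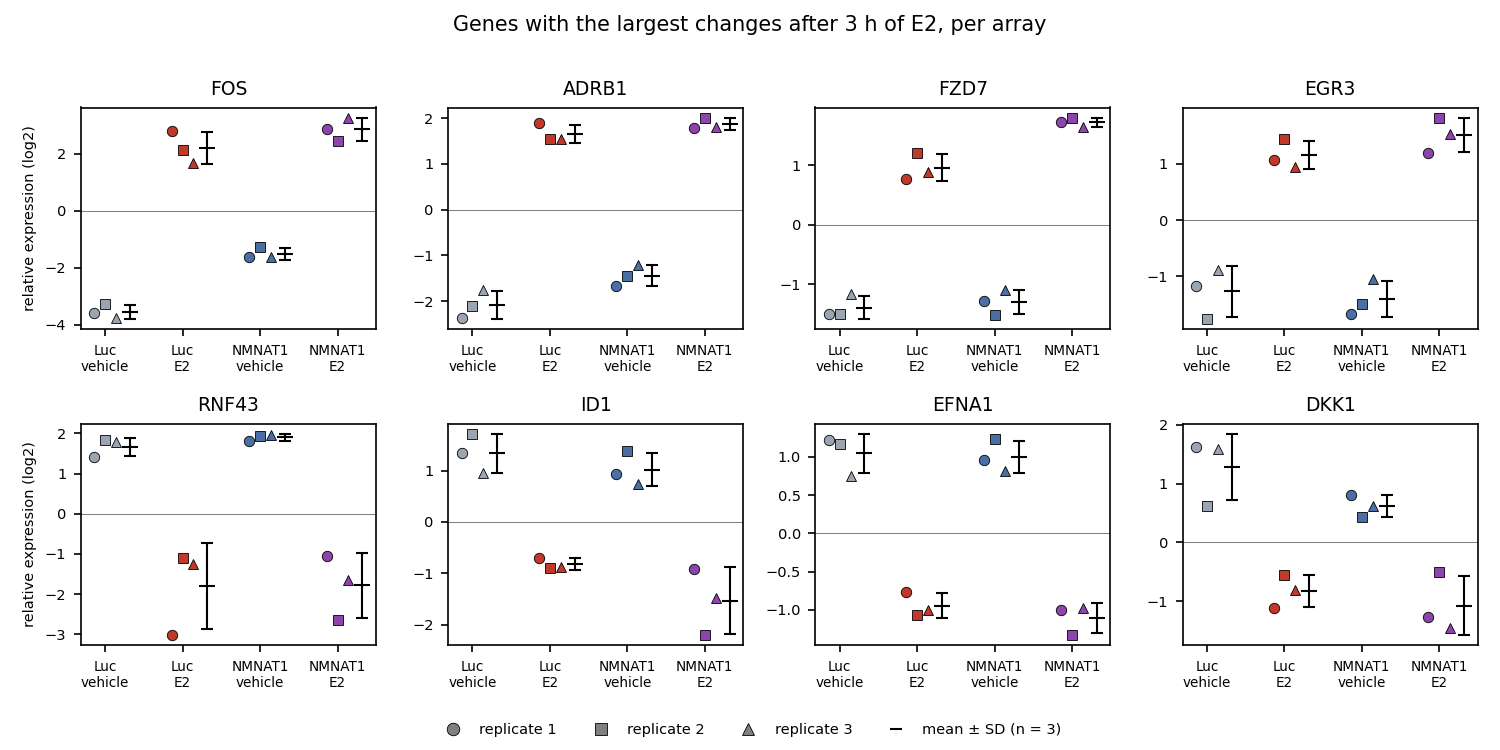
Relative expression (log2, vertical axis) of 8 genes on each of the 12 arrays, by shRNA and treatment (horizontal axis); symbols mark the replicate and the bar beside them the mean ± SD (n = 3). In FOS, for example, the mean moved by 5.74 in luciferase shRNA cells and by 4.37 in NMNAT1 shRNA cells on the log2 scale, with every E2 array above every vehicle array.

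Gene lists fixed before the data were examined placed these changes in groups. Of 38 measured genes on a list of early E2-induced genes, 29 rose and 0 fell (31 rose adjusted over the list alone). They included the progesterone receptor PGR (log2 2.26 ± 0.13), the carbonic anhydrase CA12 (2.17 ± 0.09), the ubiquitin ligase SIAH2 (1.83 ± 0.08) and GREB1 (1.49 ± 0.22), and the list passed camera with an adjusted p of 1.58e-33 (adjusted p = 0.00074 with an estimated correlation). Of 20 genes on a list of early E2-repressed genes, 9 fell and 2 rose (11 and 2 adjusted over the list alone). CCNG2, a cyclin that restrains the cell cycle, fell by 1.92 ± 0.10 on the log2 scale, NEDD9 fell by 1.35 ± 0.08 and the pro-apoptotic gene BIK fell by 1.43 ± 0.17, whereas the transcription factors KLF4 (1.25 ± 0.09) and BCL6 (1.10 ± 0.10) rose. That list passed downwards (adjusted p = 5.89e-06, and adjusted p = 0.00803 with an estimated correlation). Of 24 ribosome biogenesis genes 10 rose and 0 fell (17 and 0 adjusted over the list alone), among them the nucleolar helicase DDX21 (0.79 ± 0.11), RRS1 (0.74 ± 0.12), POLR1C (0.59 ± 0.08) and WDR12 (0.43 ± 0.06). The list passed upwards (adjusted p = 4.08e-11, and adjusted p = 0.00137 with an estimated correlation). Of 15 FOXO target genes 7 fell and 2 rose (7 and 3 adjusted over the list alone): TRIB1 fell by 1.63 ± 0.14, PIK3IP1 fell by 1.46 ± 0.12 and SESN1 fell by 1.07 ± 0.09, and BCL6 and CITED2 (0.45 ± 0.10) rose. This list passed downwards (adjusted p = 0.00127, and adjusted p = 0.0329 with an estimated correlation). It shares CCNG2, TXNIP and BCL6 with the E2-repressed list.

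A further 8 lists passed camera for E2 with its preset correlation and did not pass with an estimated one. Several members named for them are on other lists too. XBP1 is on the E2-induced list, SMAD6 on the E2-repressed list, and SESN1 and GADD45A on the FOXO list. ATF3 and IER3 are on the list of immediate early genes, and HK2 and SLC2A1 on that of hypoxia-inducible genes. Of 22 unfolded protein response genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them CHAC1 (log2 2.29 ± 0.14), ATF3 (1.54 ± 0.12) and XBP1 (0.74 ± 0.08), at an adjusted p of 0.00137 (adjusted p = 0.109 with an estimated correlation). Of 19 TGF-beta target genes 5 fell and 1 rose (6 and 1 adjusted over the list alone), at an adjusted p of 0.00789 (adjusted p = 0.0948 with an estimated correlation). The 5 were ID1, ID2, ID3, SMAD6 and TGIF1, of which the ID genes and SMAD6 are also known targets of BMP signaling, and BAMBI rose. Of 18 NF-kappaB targets, IER3 and NFKBIA fell and 0 rose (2 and 0 adjusted over the list alone), at an adjusted p of 0.0151 (adjusted p = 0.0948 with an estimated correlation). Of 16 heat shock genes HSPB8 and FKBP4, both also on the E2-induced list, rose (4 rose and 1 fell adjusted over the list alone), at an adjusted p of 0.0151 (adjusted p = 0.0948 with an estimated correlation). Of 18 glycolysis genes HK2, SLC2A1 and HK1 rose and 0 fell (4 and 0 adjusted over the list alone), at an adjusted p of 0.0375 (adjusted p = 0.455 with an estimated correlation, and 0.0676 in quantile-normalized values). Of 19 p53 targets SESN1, CDKN1A, GADD45A and FAS fell and AEN and MDM2 rose (6 fell and 2 rose adjusted over the list alone), at an adjusted p of 0.0388 (adjusted p = 0.239 with an estimated correlation, and 0.0542 with the replicate block). Neither 30 G2/M genes nor 25 ribosomal protein genes held a member that passed, over all genes or adjusted over the list alone. Their medians were -0.09 and 0.15, with camera adjusted p of 0.00148 and 0.00701 (adjusted p = 0.281 and 0.616 with an estimated correlation). Fry, which asks whether a list moves on balance in 1 direction, called 15 lists for E2, 11 of the 12 that passed camera and not the ribosomal proteins (adjusted p = 0.199). The 3' minus 5' signal of the GAPDH control transcript, a sign of RNA quality, was 0.17 ± 0.23 (SD of 6 paired differences, log2) higher on the E2 arrays (exact two-sided sign-flip p = 0.0312, the smallest that 6 pairs allow, and 0.0938 after Benjamini-Hochberg adjustment over 3 such tests).

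The next comparison asked whether E2 acted alike in cells with either shRNA. In luciferase shRNA cells 321 probe sets passed, 185 higher and 136 lower, and in NMNAT1 shRNA cells 374 passed, 256 higher and 118 lower. With each array centred on its median these were 195 higher and 141 lower, and 215 higher and 141 lower. PGR moved by 2.12 and 2.41 on the log2 scale in the 2 kinds of cells, EGR3 by 2.42 and 2.91, and ID2 (201565_s_at) moved by -2.29 and -2.23. Of the 321 probe sets, 300 (93.5%) had the same sign in the NMNAT1 shRNA cells, where their change was a median 0.94 of that in luciferase shRNA cells. Of the 374, 362 (96.8%) had the same sign in luciferase shRNA cells, with a median ratio of 0.85. Over all 22232 probe sets, 13416 (60.3%) had the same sign. A ratio below 1 is also what selection on 1 side of a noisy comparison gives. Both sets of arrays called 140 probe sets higher and 72 lower, where independent lists of these lengths would share 2.13 and 0.72. Both tests used the same estimate of spread for each probe set, which favours probe sets with a small spread in both lists. The numbers for independent lists are therefore too low a reference. Across all 22232 probe sets the correlation of the E2 effects was 0.27 (Pearson; Spearman 0.27), and across the 321 it was 0.84. Genes are not independent replicates, and no array is shared between the 2 effects. With each of the 6 populations as a block 88 and 107 probe sets passed, and with only the 6 arrays compared 0 passed in either. Without any 1 array between 49 and 285 passed in luciferase shRNA cells and between 83 and 352 in NMNAT1 shRNA cells.

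**Figure D2:**
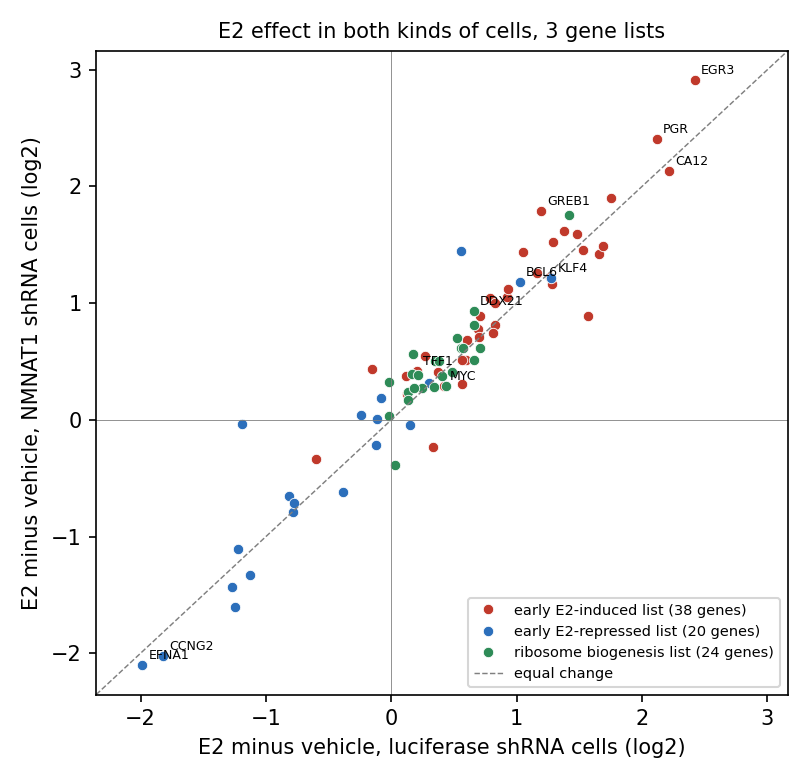
E2 minus vehicle (log2) in luciferase shRNA cells (horizontal axis) and NMNAT1 shRNA cells (vertical axis) for the genes of 3 lists, 1 point per gene, with the dashed line at equal change. EGR3 lies at 2.42 and 2.91 and PGR at 2.12 and 2.41, and CCNG2 and EFNA1 lie at the lower left.

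The NMNAT1 shRNA itself was compared with the luciferase shRNA, averaged over vehicle and E2. CAV1, the main structural protein of caveolae, was lower in NMNAT1 shRNA cells at both of its probe sets, by 1.85-fold (203065_s_at, log2 -0.89 ± 0.08, adjusted p = 0.0349) and by log2 -1.10 ± 0.10 (212097_at, adjusted p = 0.0349). DIAPH2, a formin that nucleates actin filaments, was 1.91-fold lower (205726_at, log2 -0.93 ± 0.10, adjusted p = 0.0432), and PCDH7, a protocadherin, was 1.74-fold higher (205534_at, log2 0.80 ± 0.08, adjusted p = 0.0432). For DIAPH2 1 of 3 probe sets passed and for PCDH7 1 of 4. Probe set 213777_s_at, which has no gene listed here and was singled out after its values were seen, was lower by log2 -1.98 ± 0.21 (adjusted p = 0.0458). These 5 probe sets, 1 higher and 4 lower, were all that passed, and each differed the same way in 6 of 6 pairs, which are 3 pairs of cell populations measured without and with E2. The test counts the 2 arrays of a population as separate replicates, so its p can be too small. With the 2 arrays of each population averaged 0 passed (lowest adjusted p = 0.495, with 3 residual degrees of freedom), and with the population as a random block 0 passed (lowest adjusted p = 0.0533, for CAV1). With genes in place of probe sets CAV1 alone passed of 11963 (log2 -0.99 ± 0.07, adjusted p = 0.00269), and it passed with that random block (adjusted p = 0.00442) but not with averaged populations (adjusted p = 0.423). The genes next in p did not pass: SULF1 (log2 -1.95, adjusted p = 0.0696), PKIA (-0.74, adjusted p = 0.0711) and TGFB2 (-1.20, adjusted p = 0.0754) below, and ATXN10 (0.70, adjusted p = 0.0797), RHOBTB3 (0.60, adjusted p = 0.0797), STC1 (0.81, adjusted p = 0.0993) and MPC2 (0.48, adjusted p = 0.0993) above. CAV1 also rose with E2, by log2 0.66 and 0.77 at its 2 probe sets, which were the only probe sets called for both averaged effects (0.11 expected of independent lists for that pair of directions). Both tests used the same estimate of spread for each probe set, so 0.11 is too low a reference. With the replicate number as a block 3 probe sets passed, 0 higher and 3 lower, and the 2 shared with the 5 were those of CAV1. PCDH7 and DIAPH2 (adjusted p = 0.0561 for both) and 213777_s_at (adjusted p = 0.0676) did not pass with that block, and PCDH7 did not in quantile-normalized values (adjusted p = 0.0555), where 5 passed, 0 higher and 5 lower, 4 of them shared. Without any 1 of the 3 replicates 0 passed, and without any 1 array between 0 and 2.

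**Figure D3:**
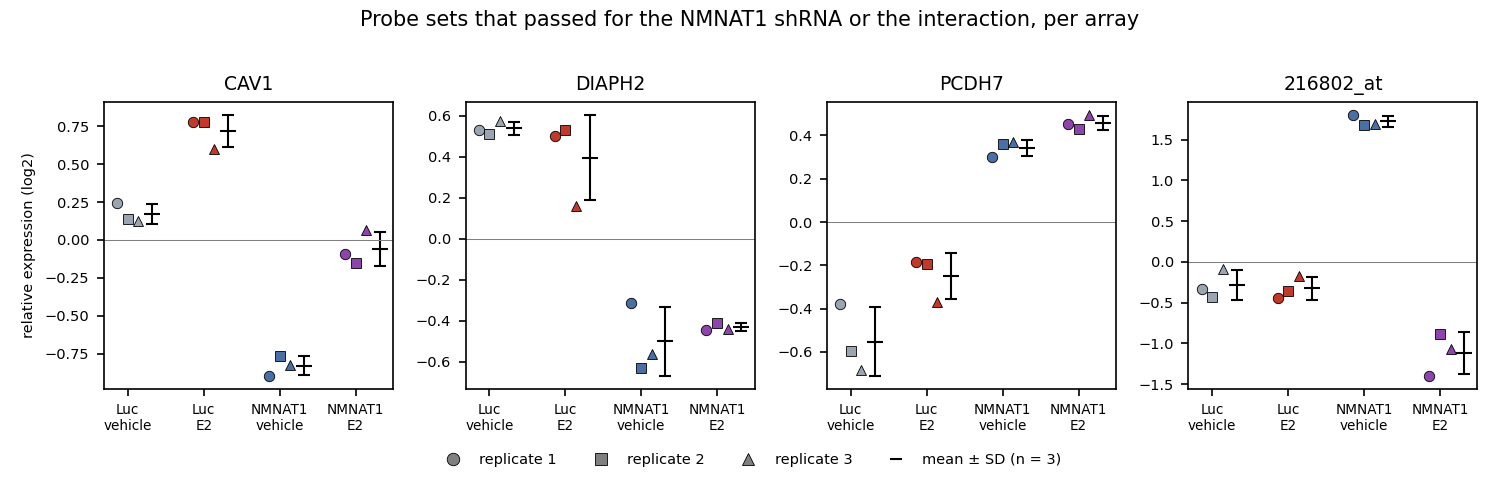
Relative expression (log2, vertical axis) on each of the 12 arrays by shRNA and treatment (horizontal axis) for CAV1 (203065_s_at), DIAPH2 (205726_at), PCDH7 (205534_at) and probe set 216802_at; symbols mark the replicate and the bar beside them the mean ± SD (n = 3). CAV1 averaged 0.17 and 0.72 in luciferase shRNA cells without and with E2, and -0.83 and -0.06 in NMNAT1 shRNA cells.

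By treatment, the shRNA comparison called 1 probe set in vehicle and 0 in E2. The 1 in vehicle was 216802_at (no gene listed here, singled out after its values were seen), higher by log2 2.00 ± 0.17 in NMNAT1 shRNA cells (adjusted p = 0.0259). It did not pass with only the 6 arrays compared (adjusted p = 0.489) or without any 1 of the 3 replicates (adjusted p between 0.245 and 0.443), and of the single arrays only replicate 3 of luciferase E2 and replicate 2 of NMNAT1 E2 could be left out without ending the call (adjusted p = 0.0453 and 0.0190 without them). With genes in place of probe sets, CAV1 alone passed in vehicle (log2 -1.21 ± 0.10, adjusted p = 0.00937) and 0 genes in E2 (CAV1 -0.78 ± 0.10, adjusted p = 0.243), and the interaction test of CAV1 did not pass (adjusted p = 0.923). In E2 the lowest adjusted p from limma over probe sets was 0.172, with 1990 probe sets at an unadjusted p under 0.05.

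No gene list passed camera for the averaged shRNA effect. On a list of basal and mesenchymal markers, 1 of 18 genes (CAV1) fell and 0 rose, the same adjusted over the list alone (median -0.06, adjusted p = 0.218). Of 15 NAD synthesis genes 0 passed over all genes, and 2 were higher and 3 lower adjusted over the list alone, among them the kynurenine pathway gene KYNU (0.51 ± 0.11). Of 17 NAD-consuming enzymes 0 passed either way. The luminal marker TFF3 (log2 -0.90 ± 0.13, adjusted p = 0.0893) and FOS (1.34 ± 0.22, adjusted p = 0.0948) did not pass. Fry called 2 of the 24 lists: ribosome biogenesis (adjusted p = 0.0262, median 0.07) and the basal and mesenchymal markers (adjusted p = 0.0277), neither of them with averaged populations (adjusted p = 0.393 and 0.421). The 3' minus 5' signal of the ACTB control transcript was 0.26 ± 0.31 (SD of 3 differences between matched populations, log2) higher in NMNAT1 shRNA cells (exact two-sided sign-flip p = 0.25, the smallest that 3 pairs allow).

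The last comparison asked whether the shRNA changed the response to E2. In limma's interaction test 0 named genes and 1 probe set passed, with 1047 at an unadjusted p under 0.05. Probe set 216802_at moved by log2 -0.04 with E2 in luciferase shRNA cells and by -2.84 in NMNAT1 shRNA cells, an interaction of -2.80 ± 0.23 (adjusted p = 0.0290, the same way in 3 of 3 pairs). It did not pass with the replicate number as a block (adjusted p = 0.0524), and of the single arrays only 1, replicate 2 of NMNAT1 E2, could be left out without ending the call (adjusted p = 0.0250 without it). The 10 genes with the lowest p did not pass. OPRM1 (log2 -3.33), SERPINB10 (-3.34), CACNA1H (-2.20), ANTXR1 (-2.86), NFKBIB (-2.18) and PIK3CG (-6.04) had lower E2 effects in NMNAT1 shRNA cells, and MYCN (2.12), MYO7A (1.89), LCAT (1.24) and NECTIN1 (2.15) higher ones, with adjusted p between 0.303 and 0.624. Each value is from 1 probe set. The other sign was found at 3 of 4 probe sets of MYO7A, 1 of 2 of LCAT and of PIK3CG, and 1 of 3 of MYCN and of OPRM1. No gene list passed camera for the interaction, where the lowest adjusted p was 0.326. In simulated data with 200 changed probe sets the interaction test recovered 6.97% of 2-fold and 25.3% of 4-fold differences, and 8.57% of its calls were false. It made 70 calls over 3 simulations, against 1 in the real data, so the adjusted threshold was easier to pass there. The real recovery can therefore be lower.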

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

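The ratio of rises called after recentring, the neighbours of each named gene and the splits by cell population for the averaged shRNA effect were tests chosen after the result was seen; the other tests were fixed before their results, the one on the neighbours of 3 named genes together after that on all genes had been seen.

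Probe set 216802_at stood out because its E2 effect differed between the 2 kinds of cells by the interaction test, with a value of -2.80. No gene is listed for it here. It averaged 1.72 ± 0.07 (SD, n = 3) in NMNAT1 shRNA cells without E2 and -1.12 ± 0.26 with it, against -0.28 ± 0.18 and -0.32 ± 0.14 in luciferase shRNA cells. Of the 10 splits of the 6 cell populations 2 called as many probe sets, the real one calling 1 and the highest other 1, and 10 splits are too few for a share under 0.05.

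The 5 probe sets that passed for the NMNAT1 shRNA form the first pattern. The shRNA was given to 6 cell populations, which make 10 splits into 3 and 3, too few for a share under 0.05. In a model with additive terms the real split called 12 and the highest other 16, so 2 of the 10 called as many. The split with 16 parts 1 of the 3 matched pairs, with luciferase population 1 and both populations on U133 Plus 2.0 arrays on 1 side. Platform was a covariate, so this split compares luciferase population 1 with the other populations on U133A 2.0 arrays. Its 16 calls are therefore not a platform difference. Of the other 3 splits that part all 3 pairs the highest called 1. Splits that part the 2 arrays of a population called fewer: of 100 drawn from those of 12 arrays into 6 and 6 only the real one called as many (value 1) and the highest other called 3, and of the 32 that part every matched pair of arrays the highest other called 2. They treat the vehicle and E2 arrays of a population as independent, which makes them no test for this effect, although the prediction for the 100 was met. With the 3' minus 5' signal as a covariate the 5 changes were a median 0.997 of those without it (between 0.95 and 1.07), as predicted without RNA degradation. The effect of the covariate is estimated within groups, and these probe sets had passed through their small spread within groups, which keeps the ratio near 1 either way. The ratio therefore decides nothing about RNA degradation, which stays open. With the covariate 0 of the 5 still passed, because the median SE rose from 0.098 to 0.105 and a degree of freedom was spent. A copy number change was looked for in the 5 nearest measured genes on each side of the 3 named genes. These 30 neighbours had shRNA effects at a median 0.0747 ± 0.138 (SE) of the gene's own, as predicted without such a change. Taken singly the ratios were 0.0374 ± 0.164 for CAV1, 0.350 ± 0.293 for DIAPH2 and 0.0331 ± 0.265 for PCDH7, which do not differ beyond their errors. The values hold no signal level, so neighbours without detectable signal would show no shared change whatever the copy number. The ratios therefore decide nothing, and the errors for DIAPH2 and PCDH7 are also too wide. A copy number change stays open for the 3 genes and for 213777_s_at, which has no gene. The mean rank correlation of -0.000744 between genes 3 to 10 places apart averages over all genes and decides nothing for these. An effect of the NMNAT1 shRNA, of what it targets besides NMNAT1, or of differences between separately infected populations stays open, as untested.

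The second pattern is the E2 response. Of 100 drawn splits into 6 and 6 only the real one (value 1) called as many probe sets in the additive model, 1034 against at most 5, and among the 32 splits that part every pair 1034 against at most 1, so chance can be excluded. With the 3' minus 5' covariate the 989 changes were a median 0.979 of those without it, as predicted without RNA degradation, and 100% kept their sign. These probe sets, too, had passed through a spread within groups that was small beside their change. The ratio therefore decides nothing about RNA degradation. With the covariate 579 still passed, with the median SE up from 0.118 to 0.127. For E2 in luciferase shRNA cells and in NMNAT1 shRNA cells the real splits called 321 and 374 and the highest others 3 and 1, with 1 of 10 splits as large in each, and 10 splits cannot give a share under 0.05. The same holds for the shRNA in vehicle (real 1, highest other 1, 2 of 10 as large) and in E2 (real 0, highest other 1, 10 of 10 as large). A response to E2, named by the design, is the hypothesis that remains, with RNA degradation not decided by the covariate.

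The third pattern is that more rises were called for E2 in NMNAT1 shRNA cells (256) than in luciferase shRNA cells (185), a ratio of 1.38. The medians of the NMNAT1 shRNA E2 arrays were 0.03, 0.08 and 0.06. After centring each array on its median the ratio was 1.10, but centring evens rises and falls whether a shift is technical or real and the medians had been seen before, so this decides nothing about an array-wide shift, which stays open. No biological explanation was tested.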

How the results depend on the processing

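Recentred medians, robust empirical Bayes, the 3' to 5' covariate, population means, the random block and the probe set with the lowest residual SD were chosen after seeing the data. No named probe set, and none of the 12 gene lists called for E2, changed direction in the alternatives run, but the balance of the few shRNA calls did. Camera and fry differed in direction for some lists that neither called with E2, such as NAD synthesis and luminal markers. The cause of each value below was not tested, except for degrees of freedom. Fewer arrays or a block leave fewer, and dropping the platform term adds a degree that centring had used. Filters on dim probe sets, the floor and the brightest probe set per gene were not run, since the values hold no signal level. NMNAT1 probe sets and signal over background, which limits what dim probe sets can show, are not analysed here.

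The count for the averaged E2 effect (989) stayed within 1.5 times except with a replicate block of 6 populations (577). E2 in luciferase shRNA cells (321) gave 565 without the platform term, 545 with array weights, 88 with the replicate block of 6 populations, 539 at a threshold of 0.1 and 0 with only the groups compared. E2 in NMNAT1 shRNA cells (374) gave 651, 676, 107, 635 and 0 under the same settings and 180 with the 3' to 5' covariate. The averaged shRNA effect (5, 1 higher and 4 lower) gave 59 without the platform term, 30 higher and 29 lower, 17 with array weights, 3 with the replicate block, 32 at 0.1, 2 with robust empirical Bayes and 0 with the covariate, with the mean of the 2 arrays of each population or with the population as a random block. In vehicle (1) it gave 6 without the platform term, 3 with array weights, 2 at 0.1, 2 with the covariate and 0 with only the groups compared, and in E2 (0) it gave 3 without the platform term and 1 with the covariate. The interaction (1) gave 0 with the replicate block, 0 with the block of 6 populations and 2 with the covariate. Apart from these, the replicate block changed no count by over 1.5 times (1017, 331 and 395 for E2, 889, 284 and 341 of them shared) and, among the gene lists called for E2, ended the p53 call (adjusted p = 0.0542). Probe sets called for both averaged effects (2) numbered 19 without the platform term, 8 with array weights, 15 at 0.1 and 0 with the covariate. The correlation of the E2 effects (0.27) was 0.24 with array weights.

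Leaving out a replicate or an array gave between 58 and 844 for the averaged E2 effect, between 0 and 285 for E2 in luciferase shRNA cells, between 0 and 352 in NMNAT1 shRNA cells, between 0 and 2 for the averaged shRNA effect, between 0 and 2 in vehicle, between 0 and 1 in E2, between 0 and 3 for the interaction, between 0 and 2 for the probe sets called for both, and between 0.18 and 0.26 for the correlation. Without replicate 1, 2 or 3 the averaged E2 effect called 96, 175 and 58, E2 in luciferase shRNA cells 0, 20 and 0, and in NMNAT1 shRNA cells 0, 13 and 0. Replicate 2 is the only one on U133 Plus 2.0, so 175, 20 and 13 are the values within U133A 2.0. Of single arrays, E2 in luciferase shRNA cells moved over 1.5 times without luciferase vehicle replicates 1 to 3 (130, 49 and 111), luciferase E2 replicates 1 to 3 (210, 57 and 207) and NMNAT1 E2 replicate 3 (201). E2 in NMNAT1 shRNA cells did so without NMNAT1 vehicle replicates 1 to 3 (161, 83 and 162), NMNAT1 E2 replicates 2 and 3 (148 and 161) and luciferase vehicle replicates 2 and 3 (203 and 236) and luciferase E2 replicate 2 (231). The averaged shRNA count was 2 without luciferase vehicle replicate 3 or NMNAT1 E2 replicate 3, 1, a higher one, without NMNAT1 E2 replicate 2 and 0 without any other array. The interaction was 3 without NMNAT1 E2 replicate 2, the array with the lowest weight (0.394), and 0 without any other. When arrays are left out the probe set means are no longer 0, which changes the trend in the fit.

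Of the 12 gene lists called for E2, 4 were called with the correlation estimated per list (9 and 11 became 3 and 4 in luciferase and NMNAT1 shRNA cells). Fry called 2 lists for the averaged shRNA effect and 1 in E2 where camera called 0, and the probe set with the lowest residual SD gave 1 for the averaged effect. The p53 call also ended in quantile-normalized values and with that probe set (adjusted p = 0.0519 and 0.0552), the glycolysis call in quantile-normalized values, after recentring and with that probe set (0.0676, 0.0658 and 0.195), and the NF-kappaB call with that probe set (0.0824). Among the 24 genes named for E2, 228 results under other settings stayed past the threshold and 12 did not, and in leave-outs 251 did and 109 did not.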

Other observations

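Several lists changed in both directions with E2 and did not pass camera. Fry, which asks whether a list moves on balance in 1 direction, called 4 of them upwards: hypoxia-inducible genes (adjusted p = 0.00802), immediate early genes (adjusted p = 0.00119), the estrogen receptor and its cofactors (adjusted p = 0.000363) and basal and mesenchymal markers (adjusted p = 0.0310). Their median log2 changes were 0.039, 0.015, 0.017 and -0.059, in that order. Counted whether or not they passed, 11, 13, 9 and 8 members were higher and 10, 11, 7 and 10 lower. Of 21 hypoxia-inducible genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.270): VEGFA, the angiogenic growth factor, rose by log2 0.70 ± 0.13, the glycolytic regulator PFKFB3 by 0.94 ± 0.19 and P4HA2 by 0.67 ± 0.08, whereas EGLN3 fell by 0.64 ± 0.14 and KDM3A fell by 0.36 ± 0.08. Of 24 immediate early genes 6 rose and 3 fell (7 and 6 adjusted over the list alone; adjusted p = 0.419), with PHLDA1 at 1.35 ± 0.13 and ZFP36 at 0.49 ± 0.08, and KLF6 at -1.13 ± 0.20. Of 16 genes for the estrogen receptor and its cofactors 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.589). The transcription factors GATA3 (-1.07 ± 0.09) and FOXA1 (-0.80 ± 0.13), which open chromatin for the estrogen receptor, fell, and the corepressor NRIP1 (1.41 ± 0.13) rose. PGR, GREB1 and NRIP1, all also on the E2-induced list, were among the 4 that rose. Of 18 luminal markers 4 fell and 2 rose (4 and 3 adjusted over the list alone; adjusted p = 0.941), the claudins CLDN3 (-0.51 ± 0.12) and CLDN4 (-0.58 ± 0.14) among those that fell. Of 18 basal and mesenchymal markers CAV1 rose and CDH3 fell (2 and 2 adjusted over the list alone; adjusted p = 0.744).

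Among 15 NAD synthesis genes the nicotinamide riboside kinase NMRK1 (log2 0.81 ± 0.11) and NADSYN1 (0.44 ± 0.09) rose with E2 and 0 fell, the same adjusted over the list alone (adjusted p = 0.863), and 0 of 17 NAD-consuming enzymes passed (adjusted p = 0.526). Of 29 G1/S genes CCNE2 fell by 0.40 ± 0.08 and 0 rose, the same adjusted over the list alone (adjusted p = 0.891). The endothelial gene VWF (1.70 ± 0.37) rose as the 1 of 15 immune and endothelial markers that passed (adjusted p = 0.763). None of 28 interferon-stimulated, 30 oxidative phosphorylation or 18 cholesterol synthesis genes passed (adjusted p = 0.270, 0.452 and 0.770).

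At the looser threshold of 0.1, 15 probe sets were called for both averaged effects. TGFB2 was lower with E2 and lower with the NMNAT1 shRNA at 2 of its probe sets (209909_s_at at -1.35 and -1.20, 209908_s_at at -1.13 and -1.31), and TMPRSS3 was higher with E2 (1.22) and lower with the shRNA (-0.76). These shRNA calls count the 2 arrays of a population as separate replicates. For 209909_s_at the call ended with the population as a random block (limma adjusted p = 0.106) and with averaged populations (adjusted p = 0.522).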
